A study of Drosophila melanogaster with 6 samples.

How the data were processed

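RNA was extracted from larval brains in 6 pools, 3 of genotype ctrl and 3 of genotype CIN, each pool of 3 brains, and the replicates came from different days per the series' design text. Libraries were made from poly(A) RNA with an NEBNext Ultra II RNA kit and 13 cycles of amplification, per the labels' protocols. That kit does not mark strand, and the strand setting of the counting is not given in the sources used here. Reads of overlapping genes, and of a gene and its antisense partner, therefore cannot be told apart. The authors deposited 1 table of whole-number counts per gene and library, not normalized, with 14150 genes. The reads were trimmed with Trim Galore, aligned with STAR 2.7.10a and counted with featureCounts on the dm6 genome, per the submitters' processing notes, which name these tools and this build without their order or settings. The treatment of reads that match several places, such as the near-identical Hsp70 copies, and the annotation release are not given in the sources used here.

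Each column of the table names 1 library by a code, which the sample descriptions and titles tie to a genotype and number, and no other column was present. Symbols were matched by FlyBase gene identifier, which gave a symbol for 14074 of the 14150 genes and left 76 under their identifier. Coordinates were taken from an Ensembl annotation of the BDGP6 assembly, the assembly that dm6 names, counted from 1. Totals per library were 24700290, 26292208 and 25278697 counts in ctrl 4, 5 and 6 and 25666856, 24668180 and 26249911 in CIN 4, 5 and 6. Depth was thus alike between groups, and 110 genes had no count. CPM values are counts scaled to the TMM-scaled library size, computed from the deposited counts.

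The genotypes were compared with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 10074, and libraries were scaled by TMM. The test was the quasi-likelihood F test (glmQLFit, glmQLFTest) on genotype alone, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The SE of a log2 fold change was taken as its size divided by the square root of F. The common biological coefficient of variation was 0.321. With 3 libraries per group, an exact permutation test could not go below 0.1 for a single value, so no such test was run for single genes. The p-values measure the spread between pools of brains from different days.

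Gene lists were fixed by name for 36 groups: spindle checkpoint, mitosis, DNA replication, neuroblast, temporal factor, ganglion mother cell, neuron, glia and optic lobe genes, then proteasome, heat shock, endoplasmic reticulum, integrated stress response, autophagy, oxidative phosphorylation, mitochondrially encoded, mitochondrial chaperone, mitochondrial ribosome, cytosolic ribosome, ribosome biogenesis, aminoacyl-tRNA synthetase, glycolysis and antioxidant genes. The others were JNK, apoptosis, DNA damage, ecdysone and immune genes, and markers of fat body, hemocytes, ring gland, muscle, salivary gland, imaginal discs, cuticle and male dosage compensation. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, adjusted over the 35 lists. Beside it stand camera with an estimated correlation and fry, which tests whether members move one way. Each member was also adjusted over its list alone. Some markers of other tissues are expressed in the brain too, so a list's level is no pure measure of tissue.

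The lists, the test, its design, the other settings and the rule for named genes were fixed before the data were examined. The rule names Bub3. It takes up to 10 rises and up to 10 falls, those largest among called genes of one sign in the 3 batches and a mean of at least 5 CPM. From each list it takes up to 3 called members, or the 2 most abundant where none was called. Other genes named are said to be chosen after their values were seen.

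The batch number is given by the labels for both genotypes, and the replicates came from different days, so the numbers pair the libraries. The check was the correlation across genes of the deviations of same-numbered libraries from their group means, which was 0.038, -0.062 and 0.175 for 4, 5 and 6. By this measure ctrl 6 and CIN 6 were each other's best partner in the other genotype. CIN 4, ctrl 5 and CIN 5 had their best partner under another number. The values thus show little of a shared batch for 4 and 5, and the pairing there rests on the labels. The labels give a batch, but no source used here says whether the authors fitted it. The fit without the block was set as the main one, with the block as another setting. The other settings were RLE size factors, no TMM, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the batch as a replicate block, each library left out, and a 2-fold minimum. Robust estimation, leaving out both ctrl 4 and CIN 5, and the ring gland level as a covariate were added after seeing the data. Ring gland markers had a median log2 fold change of 0.08 between the genotypes. Calls that hold with this covariate therefore say little about carried tissue. Fold intervals of nearly absent genes are exact binomial intervals at 95% of the summed counts and cover counting error only.

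The fits were tested on simulated data for this comparison, drawn from the means and library sizes of the 10074 tested genes, of which 9919 passed the filter again. The 200 changed genes were picked among genes with a mean of at least 5 CPM, so the recovery does not cover genes of lower abundance. Of 100 genes changed 2-fold, 36% were recovered, and of 100 changed 4-fold, 98%, with 4 false calls among 9689 unchanged genes. A set of 30 genes shifted 1.5-fold gave a camera p of 1.59e-18 and an unshifted set 0.972. The simulated genes were drawn independently, so this does not test camera on lists whose members move together. In the real data the estimated correlation ran from -0.0061 for apoptosis and p53 genes to 0.85 for cytosolic ribosomal proteins, against the preset 0.01.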

Results

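Gene expression was measured by RNA-seq of polyadenylated RNA from brains of female Drosophila melanogaster larvae at the late L3 stage, 96 h after egg laying, kept at 29 °C. The worniu-gal4 driver switches on transgenes in neuroblasts, the neural stem cells of the fly brain. In the ctrl group it drove an RNAi transgene against gfp, a gene that flies lack. In the CIN group, named for the chromosomal instability in the title of the series, it drove one against Bub3, a component of the spindle assembly checkpoint that delays chromosome separation until all chromosomes are attached. Each group held 3 libraries, 1 in each of the batches 4, 5 and 6, and each library was made from 3 brains. The deposited table gave 24668180 to 26292208 counts per library over 14150 genes, and 10074 genes passed the expression filter.

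Across the tested genes, the libraries were no more alike within a genotype than between genotypes. Pearson's r of log2 CPM across genes, which are not independent replicates, ran from 0.937 to 0.976 for pairs of the same genotype and from 0.950 to 0.979 for pairs of different genotypes. The first 2 principal components held 32.7% and 24.2% of the variance and did not part the genotypes. On component 3, with 22.1%, the ctrl libraries lay at 16.0, 34.8 and 18.4 and the CIN libraries at -30.1, -24.3 and -14.7 in batches 4, 5 and 6.

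Transcripts of tissues that touch the dissected brain differed widely between libraries. The list of markers of the ring gland, the endocrine gland that makes ecdysone, summed to 91.0 CPM in ctrl 4 and 104 CPM in CIN 5, against 2397 CPM in CIN 4, 1619 CPM in ctrl 5, 931 CPM in ctrl 6 and 789 CPM in CIN 6. CIN was thus higher in batch 4 and lower in batch 5. Hemocyte markers, which belong to blood cells, summed to 1839 CPM in CIN 4 and 2157 CPM in ctrl 5 and to between 450 and 761 CPM in the other 4 libraries. Some genes chosen after their values were seen were abundant in a single library. Muc11A, a mucin gene, stood at 3860 CPM in CIN 4, and Cyp4g1, a cytochrome P450 of oenocytes, at 1410 CPM in ctrl 5. Of lncRNA:roX2, an RNA of the dosage compensation complex of males, CIN 5 held 243 counts and the other 5 libraries 0 to 6, while the series describes all larvae as female. The mitochondrial ribosomal RNA mt:lrRNA took 7.56% of the counts in ctrl 5 and 3.56% to 4.81% in the other libraries.

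The comparison of CIN with ctrl asked which genes and gene groups differ between larval brains with Bub3 RNAi in neuroblasts and those with the gfp RNAi control. Bub3 itself, at 3R:29674007-29675421 in dm6 coordinates, measured 149, 123 and 144 CPM in ctrl 4, 5 and 6 and 80.2, 96.5 and 91.5 CPM in CIN 4, 5 and 6. It was thus lower in CIN in all 3 batches, with means of 139 ± 13.8 and 89.4 ± 8.31 CPM (SD, n = 3), a 1.55-fold difference. Its log2 fold change was -0.63 ± 0.13 (SE), which did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.333) and did pass DESeq2 (log2 fold change -0.63, adjusted p = 0.00364). Bub3 overlaps the tested gene ppk19 on the opposite strand, so its counts may share reads with that gene. The dissected brains hold neurons and glia besides neuroblasts.

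In CIN brains, 5 genes rose and 5 fell, all at least 2-fold and all with the same sign in each of the 3 batches. The falls included pros, the homeodomain factor that drives differentiation of neuroblast daughter cells, and dati, a zinc finger transcription factor. The rises included Gadd45, a stress-inducible gene of the growth arrest and DNA damage family, and its neighbour Adk3. At an unadjusted p under 0.05, where chance would give about 5% of the tested genes, 416 genes were higher and 379 lower. Other splits of the 6 libraries into 3 and 3 gave 134 to 1059 genes in all, against 795 for the real one. An excess over 5% therefore does not by itself show an effect of genotype.

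The most abundant of these genes was pros, at 3R:11328480-11407627, which fell from 4506 ± 326 CPM in ctrl to 989 ± 279 CPM in CIN (SD, n = 3). Its log2 fold change was -2.19 ± 0.22 (SE; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0422). The gene dati, at 4:375640-395605, fell from 111 ± 21.04 to 29.0 ± 5.64 CPM, with a log2 fold change of -1.94 ± 0.21 (edgeR, adjusted p = 0.0426). Called genes that were nearly absent from CIN libraries were Cyp4p2 and CG12607. The knockdown was driven in neuroblasts, while these counts come from whole brains. The groups also carry different RNAi transgenes. For these genes, as for all others, a difference between the fly stocks cannot be told from an effect of the knockdown. Cyp4p2, a cytochrome P450 gene at 2R:9237512-9239831, had 2436 counts over the ctrl libraries and 21 over the CIN libraries, 120-fold lower (95% exact interval 78.1 to 194; edgeR, adjusted p = 0.000712). CG12607, at 3L:4446573-4448072, had 1121 counts in ctrl and 1 in CIN, 1157-fold lower (95% exact interval 207 to 45730; edgeR, adjusted p = 0.00812). The CG12607 fold rests on that 1 count, in CIN 5. Without 1 of the other libraries it was 751- to 1309-fold lower, and without CIN 5 at least 260-fold, taking 3 counts over the group as the floor. These intervals cover counting error only. Near-absent genes that edgeR did not call, given here after their values were seen, were the pseudogene CR44383, with 164 counts in ctrl and 0 in CIN (edgeR, adjusted p = 0.0512), and Cyp4p1, next to Cyp4p2, with 755 and 19 counts (edgeR, adjusted p = 0.212). CR44383 was at least 56.4-fold lower with the same floor of 3 counts over the group, while the 95% exact interval reaches down to 45.4-fold, and Cyp4p1 was 41.01-fold lower (95% exact interval 26.1 to 68.5). DESeq2 called both (adjusted p = 1.99e-07 and 4.96e-13), and CR44383 was called in 6 of the other settings, DESeq2 among them. The remaining fall was CG32572, with a log2 fold change of -3.57 ± 0.37 (edgeR, adjusted p = 0.0422), which lay under the abundance set for named genes and is given here after its values were seen.

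Among the rises, Gadd45, at 2R:7249161-7250655, went from 5.95 ± 1.19 to 23.3 ± 3.41 CPM (SD, n = 3), a log2 fold change of 1.97 ± 0.21 (SE; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0436). Adk3, which lies 3384 bp away at 2R:7243024-7245776, went from 25.6 ± 3.93 to 70.02 ± 9.35 CPM, with a log2 fold change of 1.45 ± 0.16 (edgeR, adjusted p = 0.0480). CG18278 (2R:13408042-13409887) and CG30059 (2R:13412769-13414620) also lie close together. Their log2 fold changes were 2.06 ± 0.21 and 1.79 ± 0.18 (edgeR, adjusted p = 0.0422 for both). CG6654, at 3R:15211277-15213658, rose from 21.03 ± 1.92 to 57.8 ± 2.45 CPM, with a log2 fold change of 1.46 ± 0.12 (edgeR, adjusted p = 0.0169). Of the 10 genes, Cyp4p2, CG6654, CG30059, pros and CG32572 each overlap 1 tested gene on the opposite strand, so their counts may share reads with it.

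**Figure D1:**
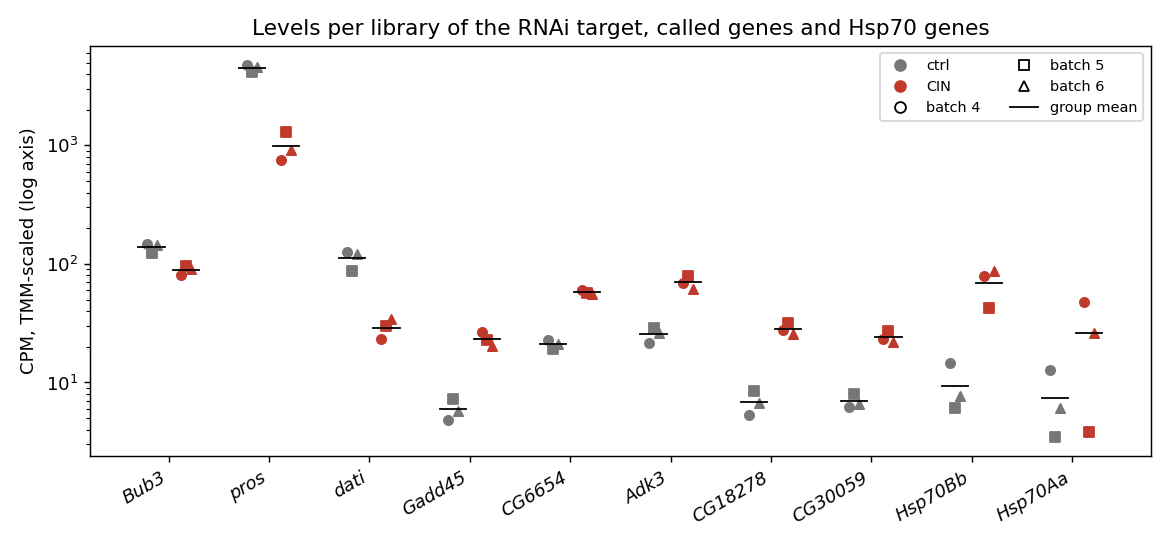
Levels of Bub3, of called genes and of 2 Hsp70 copies in each library, in TMM-scaled CPM on a log axis, with ctrl in grey, CIN in red, symbols for batches 4, 5 and 6 and bars for group means. The pros points of ctrl lie at 4160 to 4808 CPM and those of CIN at 759 to 1299 CPM, while Hsp70Aa of batch 5 stays near its ctrl level.

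The number of calls depended on single libraries and on the treatment of batch. With batch as a replicate block, edgeR called 0 genes higher and 0 lower (lowest adjusted p = 0.0557), against 473 higher and 401 lower at an unadjusted p under 0.05, and 52 higher and 55 lower by DESeq2 without the block. Without ctrl 4, ctrl 5, ctrl 6, CIN 4, CIN 5 or CIN 6, edgeR called 2, 1, 1, 2, 3 and 1 genes lower and 0 higher each time, while 261 to 551 genes were higher at an unadjusted p under 0.05. Cyp4p2 was called in each of these 6 fits. Without both ctrl 4 and CIN 5, 4 genes were called higher and 3 lower, 3 of them among the 10.

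The region around pros held further low values. The long non-coding RNA lncRNA:cherub, at 3R:11247631-11256123, measured 6015 ± 3150 CPM in ctrl and 1343 ± 605 CPM in CIN (SD, n = 3), a log2 fold change of -2.16 ± 0.49 (SE) that did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.393) and passed DESeq2 (adjusted p = 0.000133). lncRNA:CR31386, between cherub and pros, had a log2 fold change of -2.15 ± 0.41 (edgeR, adjusted p = 0.289; DESeq2, adjusted p = 0.000139). lncRNA:CR46008, which lies inside pros on the opposite strand, had one of -2.27 ± 0.27 (edgeR, adjusted p = 0.0525; DESeq2, adjusted p = 3.33e-11), was also called by edgeR with the 1 CPM filter and with robust estimation (adjusted p = 0.0454 and 0.0487), and its reads cannot be told from those of pros without strand. Of the 28 tested genes within 100 kb of pros, these 3, chosen after their values were seen, were at an unadjusted p under 0.01.

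**Figure D2:**
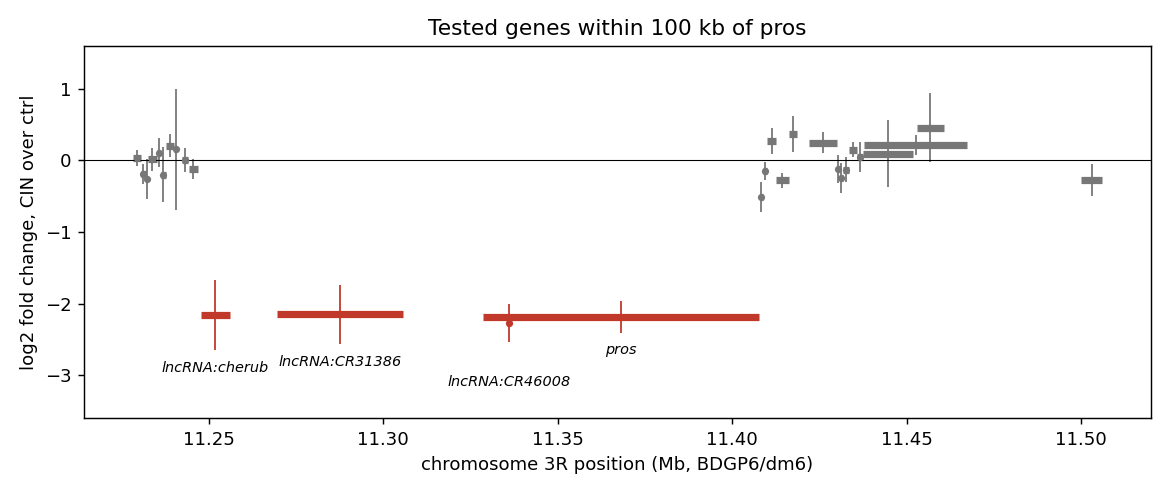
Log2 fold change of CIN over ctrl for pros and the 28 tested genes within 100 kb of it, against position on chromosome 3R in Mb. Horizontal bars span each gene, vertical lines show ± 1 SE, and pros with 3 non-coding genes in red lies between -2.27 and -2.15 while the flanking genes in grey lie near 0.

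Lists of proliferation genes fell as sets in CIN, by small amounts. In the DNA replication list, 33 of 34 tested members had negative log2 fold changes, with a median of -0.26 (SD 0.14 over members; camera, adjusted p = 3.05e-07, against adjusted p = 0.633 with an estimated correlation). The mitosis and cell cycle list had 27 of 35 negative members and a median of -0.23 (camera, adjusted p = 0.00023, against adjusted p = 0.658 with an estimated correlation). The spindle checkpoint and kinetochore list had 19 of 22 negative members and a median of -0.20 (camera, adjusted p = 0.00175, against adjusted p = 0.633 with an estimated correlation). No member of these 3 lists passed edgeR's test over all genes or adjusted over the list alone, against 5, 2 and 3 members lower at an unadjusted p under 0.05. DESeq2 called 1 of them lower, the mitotic kinase gene aurB. PCNA, the sliding clamp of replication, had a log2 fold change of -0.22 ± 0.18 (SE), and RnrL, a ribonucleotide reductase subunit, -0.20 ± 0.15. Top2 and E2f1 had -0.18 ± 0.17 and 0.13 ± 0.16, and Incenp and fzy, genes of the chromosomal passenger complex and of anaphase, -0.28 ± 0.20 and -0.33 ± 0.13. The falls were not alike in the batches: the medians of batches 4, 5 and 6 were -0.52, -0.25 and 0.02 for DNA replication, -0.64, 0.08 and -0.01 for mitosis, and -0.46, -0.05 and 0.01 for the spindle checkpoint list. In batch 4, the ring gland markers summed to 91.0 CPM in ctrl and 2397 CPM in CIN. With the ring gland level as a covariate, a choice made after seeing the data, all 3 calls held (camera, adjusted p = 1.05e-06 for DNA replication, 0.000129 for mitosis and 0.00347 for the spindle checkpoint list). As that level differed little between the genotypes on average, the held calls say little about carried tissue. Without ctrl 4, the mitosis and the spindle checkpoint calls were lost (camera, adjusted p = 0.344 for both). Without both ctrl 4 and CIN 5, also chosen after seeing the data, all 3 were lost (camera, adjusted p = 0.12 for DNA replication, 0.194 for mitosis and 0.477 for the spindle checkpoint list).

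In the neuroblast lineages, the genes and lists that passed were lower in CIN. The neuroblast list fell as a set, with 10 of 13 members negative and a median of -0.33 (SD 0.34; camera, adjusted p = 0.0121, against adjusted p = 0.633 with an estimated correlation). None of the 13 passed edgeR's test over all genes or adjusted over the list alone, against 2 lower at an unadjusted p under 0.05 and 0 by DESeq2. Its 2 most abundant members differed in sign, with mira, an adaptor of asymmetric division, at -0.71 ± 0.28 (SE) and the transcription factor SoxN at 0.38 ± 0.20. The list of ganglion mother cell and newborn neuron markers fell too, with 5 of 8 members negative and a median of -0.42 (SD 0.89; camera, adjusted p = 0.0195, against adjusted p = 0.633 with an estimated correlation). In it 1 member, pros, fell and 7 did not pass the test, also when adjusted over the list alone. With the replicate block this list was no longer called (camera, adjusted p = 0.0894). The temporal factor list was not called as a set, with 5 members up and 5 down (camera, adjusted p = 0.209). Within it dati fell, and adjusted over the list alone so did cas, another zinc finger factor, with 149 ± 85.4 CPM in ctrl and 31.1 ± 11.3 CPM in CIN (SD, n = 3; over all genes, edgeR adjusted p = 0.366 and DESeq2 adjusted p = 2.47e-05). The batch medians were -0.80, -0.21 and 0.15 for neuroblast markers and -1.10, -0.29 and 0.01 for ganglion mother cell markers in batches 4, 5 and 6. Without ctrl 4 or CIN 4, neither list was called (camera, adjusted p = 0.229 and 0.237 for neuroblasts, 0.0635 and 0.153 for ganglion mother cells). The neuroblast call was also lost without both ctrl 4 and CIN 5 (camera, adjusted p = 0.173), while the temporal factors were called lower without CIN 5 and without both (camera, adjusted p = 0.043 and 0.0324).

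Markers of neurons, glia and the optic lobe were not called as sets. The 26 neuron markers had a median of 0.03 (camera, adjusted p = 0.899), with the RNA-binding protein gene fne at -0.52 ± 0.13 (SE) and the potassium channel gene Sh at 0.28 ± 0.15. None passed edgeR's test over all genes or adjusted over the list alone, against 2 lower at an unadjusted p under 0.05, and DESeq2 called fne lower. In batch 4 their median was -0.24, against 0.16 and 0.12 in batches 5 and 6, and without CIN 4 they were called higher (camera, adjusted p = 0.00631). The 16 glia markers had a median of 0.17 (camera, adjusted p = 0.0843). Of them, 0 passed edgeR's test over all genes and 1 adjusted over the list alone, the FGF receptor gene htl, which was also the 1 member called by DESeq2, at 24.3 ± 2.09 CPM in ctrl and 37.4 ± 1.53 CPM in CIN (SD, n = 3). The abundant glial genes Gs2 and Mdr65 had log2 fold changes of 0.21 ± 0.33 and -0.09 ± 0.39 (SE). The glia list was called higher without ctrl 5, without CIN 5 and without both ctrl 4 and CIN 5 (camera, adjusted p = 0.0283, 0.000738 and 0.00110). The 18 optic lobe markers had a median of -0.01 (camera, adjusted p = 0.639), with hth at -0.11 ± 0.17 and ap at 0.65 ± 0.33, and 0 of them passed edgeR's test over all genes or adjusted over the list alone, against 2 higher at an unadjusted p under 0.05 and 0 by DESeq2.

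The series title names protein quality control and mitochondria, and lists for both moved by small amounts. Proteasome subunits fell as a set, with 33 of 34 members negative and a median of -0.12 (SD 0.07; camera, adjusted p = 0.00023, against adjusted p = 0.673 with an estimated correlation). Their batch medians were -0.15, -0.17 and -0.04 in batches 4, 5 and 6, and the call was lost without CIN 4 (camera, adjusted p = 0.237). Rpn2 and Prosalpha1 had log2 fold changes of -0.09 ± 0.13 and -0.07 ± 0.12 (SE). Endoplasmic reticulum chaperones and unfolded protein response genes rose as a set, with 22 of 24 members positive and a median of 0.13 (camera, adjusted p = 0.00307, against adjusted p = 0.633 with an estimated correlation). The chaperone Hsc70-3 had 0.25 ± 0.11 and Calr 0.05 ± 0.11. This call was lost without ctrl 4 (camera, adjusted p = 0.0787) and without both ctrl 4 and CIN 5 (camera, adjusted p = 0.12). Autophagy and lysosome genes had 21 of 29 members positive and a median of 0.04 (camera, adjusted p = 0.0447, against adjusted p = 0.633 with an estimated correlation), with cathD at 0.27 ± 0.14 and Lamp1 at 0.31 ± 0.24. That call was lost with limma-voom, the replicate block or the ring gland covariate (camera, adjusted p = 0.0512, 0.0894 and 0.0526), without ctrl 4, CIN 4 or CIN 5 (camera, adjusted p = 0.334, 0.219 and 0.0537) and without both ctrl 4 and CIN 5 (camera, adjusted p = 0.457). The integrated stress response list was not called (15 members, median 0.09; camera, adjusted p = 0.867), with Xrp1 at 0.15 ± 0.15 and crc at 0.28 ± 0.23. No member of these 4 lists passed edgeR's test over all genes or adjusted over the list alone, or was called by DESeq2. At an unadjusted p under 0.05, 1 reticulum and 1 autophagy gene were higher.

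Heat shock proteins and cytosolic chaperones were called higher as a set, with values of Hsp70 copies far above the rest. The median of the 30 members was 0.04 and 17 were positive (SD 0.96; camera, adjusted p = 0.00787, against adjusted p = 0.633 with an estimated correlation). Over all genes 0 members passed edgeR's test, against 5 higher at an unadjusted p under 0.05 and 4 by DESeq2. Adjusted over the list alone 4 were higher, Hsp70Bb, Hsp70Ba, Hsp70Bc and Hsp70Bbb, which are near-identical heat-inducible genes between which reads can be divided. Their log2 fold changes were 2.88 ± 0.41, 2.53 ± 0.39, 2.48 ± 0.39 and 2.39 ± 0.41 (SE; edgeR over all genes, adjusted p = 0.118 to 0.204). Hsp70Bb went from 9.41 ± 4.49 to 69.4 ± 23.7 CPM (SD, n = 3). The summed CPM of the 6 Hsp70 copies was 4.44-, 4.42- and 7.51-fold higher in CIN in batches 4, 5 and 6. The Hsp70A copies alone were 3.8-, 1.11- and 4.31-fold higher and the Hsp70B copies 4.74-, 5.34- and 8.77-fold. The abundant chaperones Hsc70-4 and Hsp23 had log2 fold changes of -0.06 ± 0.18 and 0.04 ± 0.27. The set call was lost without ctrl 5 or CIN 4 (camera, adjusted p = 0.0525 and 0.0767). Without both ctrl 4 and CIN 5, the 4 Hsp70B copies passed over all genes (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0162 for each).

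Genes for mitochondrial and cytosolic translation fell as sets. Mitochondrial ribosomal proteins had 70 of 71 members negative and a median of -0.24 (SD 0.14; camera, adjusted p = 1.22e-13, against adjusted p = 0.633 with an estimated correlation), and their batch medians were -0.11, -0.47 and -0.19 in batches 4, 5 and 6. Ribosome biogenesis factors had 25 of 25 negative and a median of -0.23 (camera, adjusted p = 1.65e-08, against adjusted p = 0.633 with an estimated correlation), with batch medians of -0.26, -0.31 and -0.10. Aminoacyl-tRNA synthetases had 18 of 20 negative and a median of -0.16 (camera, adjusted p = 0.000204, against adjusted p = 0.633 with an estimated correlation), with batch medians of -0.14, -0.22 and -0.08. These 3 lists were called in each of the 6 fits that left out 1 library, all at the preset correlation. Cytosolic ribosomal proteins had 79 of 81 negative and a median of -0.16 (camera, adjusted p = 2.18e-06, against adjusted p = 0.690 with an estimated correlation), with batch medians of 0.05, -0.50 and -0.04. Ring gland markers, with batch medians of 7.07, -5.49 and -0.15, and hemocyte markers, with 3.37, -1.93 and -1.06, had the same signs as the cytosolic ribosomal proteins in batches 4, 5 and 6. The cytosolic call held with the ring gland level as a covariate (camera, adjusted p = 4.63e-07) and was lost without both ctrl 4 and CIN 5 (camera, adjusted p = 0.187). Holding with this covariate says little about carried tissue, as the ring gland level differed little between the genotypes on average. No member of these 4 lists passed edgeR's test over all genes or adjusted over the list alone, or was called by DESeq2. At an unadjusted p under 0.05, 18 mitochondrial ribosomal proteins, 6 biogenesis factors, 1 synthetase and 0 cytosolic ribosomal proteins were lower. The abundant members mRpS30 and mRpL28 had log2 fold changes of -0.14 ± 0.13 and -0.14 ± 0.15 (SE), RpL7A and sta -0.24 ± 0.18 and -0.23 ± 0.24, Nop60B and Non1 -0.24 ± 0.14 and -0.07 ± 0.34, and ThrRS and LysRS -0.22 ± 0.11 and -0.24 ± 0.13.

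Respiratory chain lists fell as sets with camera's preset correlation and were not called with an estimated one (adjusted p = 0.673 for nuclear-encoded and 0.655 for mitochondrially encoded genes). Their medians lay below 0 in batches 5 and 6 and above 0 in batch 4, the signs of the ring gland and hemocyte markers (7.07, -5.49 and -0.15, and 3.37, -1.93 and -1.06 in batches 4, 5 and 6). Nuclear-encoded oxidative phosphorylation subunits had 62 of 67 members negative and a median of -0.17 (SD 0.09; camera, adjusted p = 1.22e-06). Their batch medians were 0.14, -0.59 and -0.11 in batches 4, 5 and 6, and the call was lost without CIN 5 (camera, adjusted p = 0.143). Mitochondrially encoded genes had 12 of 13 negative and a median of -0.32 (SD 0.35; camera, adjusted p = 0.0069), with batch medians of 0.20, -0.90 and -0.33. That call was lost without ctrl 5, the library with 7.56% of counts on mt:lrRNA, and without CIN 6 (camera, adjusted p = 0.133 and 0.0577). Both respiratory calls at the preset correlation held with the ring gland level as a covariate (camera, adjusted p = 3.07e-10 for the nuclear-encoded list and 0.00266 for the mitochondrially encoded one). That level differed little between the genotypes on average, so calls that hold with it as a covariate say little about carried tissue. The ATP synthase genes ATPsynC and blw had log2 fold changes of -0.29 ± 0.17 and -0.10 ± 0.13 (SE), and mt:CoI and mt:CoIII had -0.01 ± 0.16 and -0.09 ± 0.19. Mitochondrial chaperones, proteases and quality control genes were not called (23 members, median -0.0022; camera, adjusted p = 0.941), with Hsp60A at 0.11 ± 0.27 and Hsc70-5 at -0.0022 ± 0.18. Glycolysis genes did not pass as a set (14 members, median -0.07; camera, adjusted p = 0.494), with Gapdh2 at 0.16 ± 0.32 and Ald1 at -0.13 ± 0.43. Their batch medians were 0.31, -0.81 and 0.10, and they were called lower without CIN 4 (camera, adjusted p = 0.0126) and higher without CIN 5 or without both ctrl 4 and CIN 5 (camera, adjusted p = 0.00758 and 0.0120). Glutathione S-transferases and antioxidant enzymes did not pass (38 members, median 0.23; camera, adjusted p = 0.193), with Prx2 at -0.14 ± 0.17 and Sod1 at -0.19 ± 0.29. That list was called higher with all 6 libraries and no filter on low counts (camera, adjusted p = 0.0478), without ctrl 5, CIN 5 or CIN 6 (camera, adjusted p = 0.0243, 0.000556 and 0.0397) and without both ctrl 4 and CIN 5 (camera, adjusted p = 0.00824). No member of these 5 lists passed edgeR's test over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 2 mitochondrially encoded genes were lower and 3 antioxidant genes higher, and DESeq2 called 1 antioxidant gene, GstE8, higher.

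**Figure D3:**
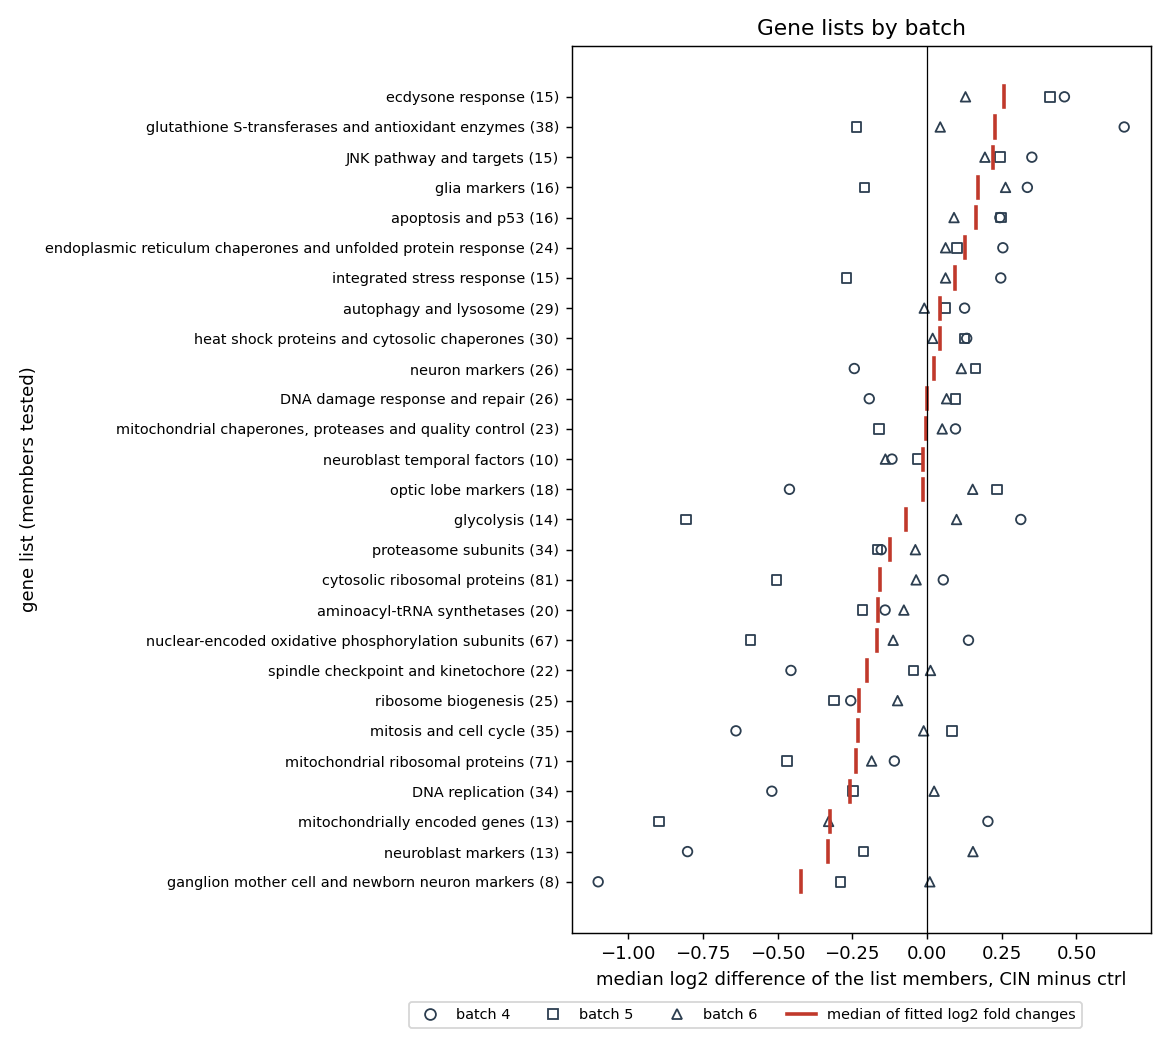
Median log2 difference between CIN and ctrl of the members of 27 gene lists in batches 4, 5 and 6 (open symbols), with the median of the fitted log2 fold changes as a red line and the number of tested members in brackets. The 3 batches lie on one side of 0 for ribosome biogenesis, at -0.26, -0.31 and -0.10, and on both sides for nuclear-encoded oxidative phosphorylation subunits, at 0.14, -0.59 and -0.11.

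JNK pathway genes, which act in stress signalling, rose as a set, with 13 of 15 members positive and a median of 0.22 (SD 0.50; camera, adjusted p = 0.000263, against adjusted p = 0.633 with an estimated correlation). The batch medians were 0.35, 0.24 and 0.19 in batches 4, 5 and 6. At the preset correlation, the list was called in each of the 6 fits without 1 library. In it 1 member rose, Gadd45, over all genes and adjusted over the list alone, and 14 did not pass. The matrix metalloprotease gene Mmp1 went from 34.8 ± 0.15 to 61.2 ± 20.1 CPM (SD, n = 3) and the JNK phosphatase gene puc from 42.7 ± 4.27 to 52.2 ± 7.77 CPM, both without passing and both chosen after their values were seen. Ecdysone response genes, which follow the moulting hormone, rose as a set with 14 of 15 members positive and a median of 0.26 (SD 0.48; camera, adjusted p = 0.00437, against adjusted p = 0.633 with an estimated correlation). The factors br and Eip75B had log2 fold changes of 0.34 ± 0.21 and 0.21 ± 0.25 (SE). The batch medians were 0.46, 0.41 and 0.13 in batches 4, 5 and 6, all positive, while those of ring gland markers were 7.07, -5.49 and -0.15. The call held with the ring gland level as a covariate (camera, adjusted p = 0.00407). That level differed little between the genotypes on average, so the held call says little about carried tissue. The ecdysone call was lost without ctrl 4 or CIN 5 (camera, adjusted p = 0.163 and 0.0536) and without both (camera, adjusted p = 0.977). Apoptosis and p53 genes did not pass (16 members, median 0.16; camera, adjusted p = 0.0813), with Diap1 at 0.04 ± 0.18. DNA damage response and repair genes did not pass (26 members, median 0.0012; camera, adjusted p = 0.788), with grp, a checkpoint kinase gene, at -0.02 ± 0.14. Immune effectors and receptors did not pass (15 members, median 0.10; camera, adjusted p = 0.639), with Tep4 and Tep2 at 1.56 ± 1.12 and 0.18 ± 0.37, and were called lower without CIN 4 (camera, adjusted p = 0.00555). In the ecdysone, apoptosis, DNA damage and immune lists, 0 members passed edgeR's test over all genes or adjusted over the list alone, against 0, 2, 1 and 1 at an unadjusted p under 0.05 and 0 in each by DESeq2.

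Markers of other tissues include sets that differed between genotypes. Salivary gland markers fell, with 7 of 7 members negative and a median of -1.97 (SD 0.43; camera, adjusted p = 0.000163, against adjusted p = 0.633 with an estimated correlation). They summed to 87.1, 34.0 and 21.7 CPM in ctrl 4, 5 and 6 and to 12.3, 19.4 and 2.90 CPM in CIN. Sgs3 and Sgs4, glue protein genes, had log2 fold changes of -2.20 ± 0.87 and -1.85 ± 0.94 (SE). Fat body markers fell, with 8 of 8 negative and a median of -1.86 (SD 0.65; camera, adjusted p = 0.00493, against adjusted p = 0.633 with an estimated correlation), and summed to 706, 279 and 218 CPM in ctrl and 213, 170 and 192 CPM in CIN. The fat body batch medians were -2.20, -1.14 and -0.47 in batches 4, 5 and 6. The fat body call was lost without ctrl 4, the library with the highest sum, and without both ctrl 4 and CIN 5 (camera, adjusted p = 0.344 and 0.822). The storage protein gene Lsp1beta had -2.40 ± 1.27 and apolpp -0.52 ± 0.16. Sets that did not pass were hemocytes (12 members, median -0.02; camera, adjusted p = 0.846), the ring gland (7 members, 0.08; adjusted p = 0.867), muscle (13 members, 0.36; adjusted p = 0.0813), imaginal discs (12 members, -0.07; adjusted p = 0.706) and cuticle (7 members, 0.41; adjusted p = 0.867). Muscle markers were called higher with the replicate block (camera, adjusted p = 0.0143), and without ctrl 4, CIN 5, CIN 6 or both ctrl 4 and CIN 5 (camera, adjusted p = 0.0403, 0.0493, 0.000654 and 0.0299). Hemocyte markers were called lower without CIN 4 (camera, adjusted p = 0.0088). The most abundant members were Col4a1 and vkg for hemocytes (-0.09 ± 0.57 and -0.03 ± 0.67), sad and spok for the ring gland (0.69 ± 2.00 and 0.01 ± 2.08), and Act87E and Act57B for muscle (0.03 ± 0.12 and 0.25 ± 0.27). They were ct and sd for discs (0.53 ± 0.21 and 0.05 ± 0.14), and Lcp1 and Lcp2 for cuticle (1.96 ± 1.58 and 1.82 ± 1.62). Of the male dosage compensation RNAs, lncRNA:roX1 alone could be tested, at 0.40 ± 0.67, with 965 CPM in CIN 5 against 153 to 452 CPM in the other libraries. No member of these 8 lists passed edgeR's test over all genes or adjusted over the list alone, or was called by DESeq2, while 3 salivary gland, 2 fat body and 5 disc genes were at an unadjusted p under 0.05.

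Of the 36 lists, 35 could be tested as sets, and 14 were called lower and 5 higher with camera's preset correlation. None of the 19 calls held with a correlation estimated from the libraries (lowest adjusted p = 0.633) or with fry, which asks whether members move one way on balance (lowest adjusted p = 0.316). In 10 of the 19 lists the medians of the 3 batches had one sign. At the preset correlation, 7 of the 19 were called in each fit without 1 library. With the ring gland level as a covariate, 18 of the 19 calls held, and autophagy was lost (camera, adjusted p = 0.0526). That level differed little between the genotypes on average, so the covariate could move the genotype effects little. Calls that hold with it therefore say little about carried tissue. Without both ctrl 4 and CIN 5, 10 of the 19 calls held. The sign of the median and of the camera test differed for 6 lists that were not called, neuron, optic lobe, imaginal disc and immune genes, mitochondrial chaperones and DNA damage response.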

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

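Robust estimation and both settings based on the ring gland were chosen after seeing the data. All 10 called genes kept their direction in every setting, and all 10 were called by DESeq2. The counts of 5 higher and 5 lower genes stayed within 1.5 times with RLE (4 and 5), without TMM, without a filter (5 and 6), with limma-voom and with a 2-fold minimum, although RLE lost Adk3, the fit without TMM dati and limma-voom CG32572. DESeq2 called 52 higher and 55 lower, and the replicate block called 0 and 0, with no cause tested for either. The block also ended 2 list calls, ganglion mother cell and autophagy genes, added muscle and changed no other. Lower genes numbered 10 with the 1 CPM filter, which tests fewer genes, 9 with robust estimation, 3 without ctrl 4 and CIN 5, and 3 with the ring gland covariate, under which 0 were higher. Leaving out single libraries, which leaves fewer samples, gave 0 to 0 higher and 1 to 3 lower. Bub3 had a log2 fold change of -0.63 under DESeq2 and passed there only, among the settings run.

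The adjusted p of the neuroblast list ran from 0.000654 to 0.237 over the fits without 1 library, and was 0.173 without ctrl 4 and CIN 5, 0.633 with an estimated correlation and 0.590 by fry. The proteasome list ran from 3.75e-07 to 0.237, with 0.673 by the estimated correlation and 0.607 by fry. Heat shock proteins ran from 0.000148 to 0.0767, with 0.633 and 0.397. Nuclear-encoded oxidative phosphorylation ran from 2.98e-13 to 0.143, with 0.673 and 0.607. Lists that were not called passed with the direction opposite to that of their test over all libraries, neuron markers higher without CIN 4 (0.00631, within 0.00631 to 0.939 over the fits without 1 library) and glycolysis higher without CIN 5 (0.00758, within 0.00758 to 0.560) and without ctrl 4 and CIN 5 (0.0120). The cause was not tested beyond the smaller number of libraries. Of the other comparisons with an alternative, 1163 for named genes kept direction and side of the threshold, 67 were weaker, 12 stronger and 83 of uncalled genes changed sign. For lists these were 417, 55, 18 and 33. Depth was 24668180 counts or more in every library, and 36% of simulated 2-fold changes in genes with a mean of at least 5 CPM were recovered with 3 libraries per group.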

Other observations

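Except for the count of called genes over the splits of the libraries, the tests of explanations below, the count of adjacent pairs over those splits included, were chosen after the result was seen. DESeq2 called 107 genes, all with one sign in the 3 batches, and most were not called by edgeR's quasi-likelihood test, so the following genes, picked from those 107 after their values were seen, rest on DESeq2 alone. No enrichment was tested, and of the fixed lists the mitosis list held 0 of the 107 and the spindle checkpoint list 1. In CIN over ctrl, the mitotic kinase gene aurB had a log2 fold change of -0.67 ± 0.18 (SE, adjusted p = 0.0240), the centriole gene ana2 -0.87 ± 0.23 (adjusted p = 0.0240), and the chromatin remodelling subunits Acf and Chrac-16 -0.76 ± 0.19 and -0.85 ± 0.21 (adjusted p = 0.00749 and 0.00794). The Mediator subunit gene MED7 had -0.84 ± 0.13 (adjusted p = 7.67e-08), and dj-1beta, a gene of oxidative stress protection, -0.81 ± 0.17 (adjusted p = 0.000287). krimp, a gene of the piRNA pathway best known from the germline, had -2.17 ± 0.34 (adjusted p = 8.37e-08), and bam, a germline differentiation gene, -1.37 ± 0.38 (adjusted p = 0.0288).

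High values in CIN by DESeq2 included the mesoderm factor twi at 1.89 ± 0.44 (SE, adjusted p = 0.00415), Wnt6 at 1.82 ± 0.50 (adjusted p = 0.0277), the adaptor gene Traf4 at 0.58 ± 0.15 (adjusted p = 0.0188) and the glutathione transferase GstE8 at 2.68 ± 0.66 (adjusted p = 0.00749). The neighbours Pex7, a peroxisome import gene, and CG13305 had -2.60 ± 0.53 and -2.35 ± 0.55 (adjusted p = 0.000252 and 0.00415). In edgeR's test none of these passed.

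With 10 splits of the 6 libraries into 3 and 3, a share under 0.05 cannot be reached. The real split gave 10 called genes, the highest of the other splits 0, and 1 split, the real one, gave as many. Of the other splits, 3 also part every batch pair, with 134 to 384 genes at an unadjusted p under 0.05 against 795 in the real split, and the 6 that keep a pair together had 161 to 1059.

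The fall of pros was the first pattern weighed. If it came wholly from fewer cells of the neuroblast lineages, the other ganglion mother cell and newborn neuron markers would fall about as far. The median of the other 7 was -0.335 (SD 0.59) against -2.19 for pros. That argues against an even loss of the cells these markers label as the whole cause. Single genes of the temporal factor list fell about as far as pros, with dati at -1.94 and cas, which edgeR did not call, at -2.26. In that list 5 members were positive and 5 negative. A loss of only some cells of these lineages stays open. Counts assigned to the overlapping tested gene, lncRNA:CR46008, came to 0.252% of the CPM of pros in ctrl. Without strand, shared reads may have been counted in pros or left out. This share therefore cannot decide whether they play a part in the fall. A local difference between the stocks at the locus stays open, since 3 of 28 tested genes within 100 kb, lncRNA:cherub among them, were low at an unadjusted p under 0.01 while the rest were not. The knockdown itself, the difference that the design names, was not tested as a cause and stays open.

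The high Hsp70 values were the second pattern. Division of counted reads between near-identical copies would not raise their sum. The lowest fold of the summed copies over the batches was 4.42, which argues against such division as the cause. The treatment of reads that match several places is not given in the sources used here. If they were left out, the sum does not cover them, and an effect of mapping stays open. A general heat shock response remains open, as the median log2 fold change of 9 other heat-inducible genes was 0.386 (SD 0.388, 7 positive), between the value of 1 it called for and 0. Many fly RNAi vectors carry hsp70 promoter or terminator sequence, so transgene reads may add to the Hsp70B copies. The lowest difference of Hsp70B minus Hsp70A on the log2 scale was 0.32 over the batches, with 2.26 in batch 5, which leaves this open because the sources used here do not describe the vectors.

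The last pattern was that genes of low p lie next to each other, as Adk3 with Gadd45 and Cyp4p2 with Cyp4p1 do. Among the 100 genes of lowest p, 6 pairs of the same direction lay within 10000 bp with no tested gene starting between them, and 11 pairs with such genes allowed, which adds CG18278 with CG30059, MED7 with TfIIFbeta and 3 pairs of near-identical Hsp70 copies. The pattern is not shown to belong to the genotypes, as the 3 other splits that part every batch pair gave up to 6 pairs by the first count (median 4) and up to 9 by the second (median 6), and the 6 splits that keep a pair together had medians of 2 and 4. By either count only 1 pair, pros with lncRNA:CR46008, overlaps in the annotation used here. That argues against reads shared by overlapping genes as the source of most pairs. The annotation release of the counting is not given, and genes as close as Cyp4p2 and Cyp4p1, 209 bp apart, could overlap in it. Reads can also be divided between the near-identical Hsp70 copies without any overlap. Whether local differences between the chromosomes of the stocks add to the pairs stays open, since they called for more pairs in the real split than in every other, which held by the second count and not by the first. Without the 3 pairs of Hsp70 copies, the second count of the real split would not exceed the 9 of the highest other split, counted with all its pairs.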
